A study of Mus musculus with 39 samples.

How the data were processed

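The authors deposited 1 file of raw counts per mouse, made with HTSeq from STAR alignments to GRCm39 after FastQC. Each file held 56980 genes and 5 summary lines. The labels gave no versions for these programs, no strand setting, no annotation release and no read filter. The 5 summary lines were kept apart and used only for the share of unassigned reads. Gene symbols came from a reference table of an earlier genome build, so no coordinates were used. Of the 56980 identifiers 52073 were matched to a symbol. A symbol shared by several identifiers was given to the identifier with the most counts.

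All 39 libraries were kept, with 19685385 to 21350610 counts each. Genes were filtered with filterByExpr of edgeR 4.0.16 by diet, which left 14658 tested genes. Libraries were scaled with TMM factors. Quasi-likelihood F tests were run on 1 model with a mean per diet, with 3 pairwise comparisons and 1 test of any difference between diets. Tests were two-sided. P values were adjusted by the method of Benjamini and Hochberg over all tested genes of a comparison, and 0.05 was the threshold. The standard error of a log2 fold change was taken as its absolute value over the square root of F. Normalised values are CPM computed with TMM factors, given as mean and SD over mice, and log2 CPM used a prior count of 2. R was version 4.3.3.

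The number of mice showing a direction is the number in the first group of a comparison that lay beyond the mean of the second group.

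Before the data were examined, 46 gene lists were written from general knowledge, and 43 had at least 5 tested genes. Of 826 symbols in the lists 83 were not tested, 71 because they fell below the filter and 12 because they were not in the name table. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01. They were tested again with the correlation estimated from the residuals, and with fry. P values of lists were adjusted over the lists of a comparison. Counts within a list were made with p values adjusted over all genes, and again with p values adjusted over the list alone. The SE of a list median was computed from the spread over its genes, taken as independent. It does not measure the spread over mice, and genes of a list are correlated.

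Genes are named by a rule fixed at the same stage. Lct, Sis, Slc5a1, Slc2a2, Slc2a5, Galk1 and Galt were followed in every comparison. The 6 genes of smallest p in each direction were named among called genes with mean log2 CPM of at least 1. Up to 4 called members of a list were named, smallest p first, and for a list past camera without called members the 3 of smallest p. Other genes in the text are list members, named to show what moved with or against a list. Some genes that this rule picks are not used here as named results, though they stay in all tests and counts.

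A list score is the mean over list genes of log2 CPM scaled to mean 0 and SD 1 over libraries. A tissue score was the mean of the scores of the stem, fibroblast and smooth muscle lists. A crypt score came from the Paneth and cell cycle lists. A regional score was the distal minus the proximal intestinal score, without genes of the lists it was used to adjust. Differences between diets in 10 library measures were tested by permutation with 100000 resamples, giving 30 tests adjusted together. The permutations did not pair mice with neighbouring title numbers. Principal components were computed on log2 CPM of the tested genes.

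The title numbers of the samples form 2 runs, 1 to 18 and 49 to 69, and each run was also analysed alone. These runs are not a labelled batch. A test of diet by run interaction was made in edgeR.

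Galactose and lactose shared the glucose group as control. The fold changes of both comparisons were therefore set against simulated groups without change, made by permuting residuals, with 1000 draws. They were also computed with the glucose group split into 7 and 6 mice, with 100 splits for the correlation and 15 for the overlap. To see how many genes groups unrelated to diet would give, the 39 libraries were put into groups of the same sizes in 60 splits, the real one included.

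Other choices, listed in advance, were DESeq2 1.42.0, limma voom with quality weights, RLE factors, library totals, robust dispersion, other filters, covariates for run, triplet and a residual component, each run alone, and fits on the 2 compared groups. After the results were seen, 6 more were added. They were covariates for the tissue score, a clock score and title number, and fits without the library with pancreatic transcripts, without 7 libraries high in interferon-induced transcripts, and without the 3 libraries lowest on the first component.

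The pipeline was tested on simulated data. In edgeR 43.3%, 34.3% and 40.3% of genes changed 1.25-fold were recovered in the 3 comparisons, 79.1%, 73.1% and 74.6% of those changed 1.5-fold, and 92.4%, 93.9% and 87.9% of those changed 2-fold. False calls were 9 of 152, 7 of 141 and 11 of 146. Genes were drawn independently in these simulations, with no differences in tissue content or between title numbers. The share of false calls in the real data may therefore differ. Libraries of the same diet were checked for duplicates on genes with at least 50 counts summed over the pair. No pair was alike, as the lowest chi-square per gene was 10.9. Pairs from different diets were not checked.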

Results

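Transcripts were counted in scraped mucosa of the proximal small intestine from 39 female C57BL/6JRccHsd mice, without the first 2 cm of the duodenum. The mice were weaned at day 21 and fed 1 of 3 diets for 3 weeks, to day 42, and were sacrificed in the fed state. The glucose diet held 32 en% glucose, the galactose diet 16 en% galactose and 16 en% glucose, and the lactose diet 32 en% lactose. All diets also held 32 en% starch, 3 en% fructose, 20 en% protein and 20 en% fat. Each diet had 13 mice, and each mouse gave 1 library. Galactose and lactose were each compared with glucose. Lactose was then compared with galactose, which sets the bound disaccharide of glucose and galactose against the same sugars given free.

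Counts assigned to genes ranged from 19685385 in galactose 4 to 21350610 in galactose 5, and 10.1% to 15.7% of reads were unassigned. Of 56980 genes 14658 passed the expression filter. Total counts did not differ between diets past the threshold, with permutation tests giving adjusted p = 0.724 for galactose and 0.0973 for lactose against glucose, and 0.256 between them. Reads without a unique alignment were 5.646% with lactose and 6.395% with glucose (permutation adjusted p = 0.0256). Ambiguous reads were 1.742% with lactose and 1.652% with galactose (permutation adjusted p = 0.0183). The 10 most abundant genes took 9.644% of counts with lactose and 10.49% with glucose (permutation adjusted p = 0.0325). Other comparisons of these measures did not pass. The TMM factors were 0.946 ± 0.0311 with lactose, 1.017 ± 0.0473 with glucose and 1.042 ± 0.0571 with galactose (SD, n = 13). They were lower with lactose than with either other diet (permutation adjusted p = 3e-04 each). Galactose against glucose did not pass (permutation adjusted p = 0.33). Diet explained 32.4% of the variance of the first principal component (17.3% of variance, permutation p = 0.00083). It explained 52.0% of the second (14.5% of variance, permutation p = 1e-05, the smallest the 100000 resamples can give). Components 3 and 4 (8.88% and 7.13% of variance) followed not diet but triplets of neighbouring title numbers, each with 1 mouse per diet, which explained 70.3% and 69.9% of them (permutation p = 2.6e-04 and 3.2e-04).

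Transcripts that mark cell types differed with diet as well. A tissue score built from stem cell, fibroblast and smooth muscle genes was -0.551 ± 0.387 in lactose mice, 0.0393 ± 0.518 in glucose mice and 0.512 ± 0.564 in galactose mice (SD, n = 13). Permutation tests gave adjusted p = 3e-04 for lactose against galactose, 0.0155 for lactose against glucose and 0.0711 for galactose against glucose. Immunoglobulin transcripts made up 0.318 ± 0.104% of counts with lactose, 0.220 ± 0.0563% with glucose and 0.157 ± 0.0565% with galactose, and all 3 differences passed by permutation (adjusted p = 0.0227 for lactose and 0.0292 for galactose against glucose, and 3e-04 between them). Mitochondrial transcripts took 3.08 ± 0.709% of counts with lactose and 4.19 ± 1.15% with glucose (permutation adjusted p = 0.0183). Library galactose 4 carried pancreatic transcripts, with 3097 CPM of Pnliprp1, 2253 CPM of Clps and 2488 CPM of Rnase1, and galactose 7 carried fewer, with 105 CPM of Pnliprp1 and 83.3 CPM of Clps. The interferon-induced gene Ifit3 exceeded 100 CPM in 7 libraries, which were galactose 3, 8 and 9, lactose 3 and 9, and glucose 8 and 9.

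A few genes that digest and carry sugars differed between the diets. Lct, which encodes lactase, was highest with galactose at 3281 ± 694 CPM, lower with glucose at 2416 ± 622 CPM and lowest with lactose at 1806 ± 592 CPM (SD, n = 13). Lactose-fed mice had 1.82-fold less Lct than galactose-fed mice (log2 -0.86, SE 0.14, edgeR adjusted p = 1.35e-05, 12 of 13 mice). The difference was -0.76 within title numbers 1 to 18 and -0.97 within 49 to 69, and it passed within both. Against glucose, Lct fell by 0.42 with lactose (SE 0.14, edgeR adjusted p = 0.0364, 11 of 13 mice). With galactose it did not pass (log2 0.44, SE 0.14, adjusted p = 0.0643, 12 of 13 mice). Both of these results lay near the threshold. The lactose result ended when the tissue score was a covariate (log2 -0.36, adjusted p = 0.187), and the galactose result passed in DESeq2 (log2 0.45, adjusted p = 0.0289) and with triplets of title numbers as a block (log2 0.46, adjusted p = 0.0259), among other choices.

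Slc5a4b, a member of the sodium-glucose cotransporter family, moved the other way. It measured 600.5 ± 130.5 CPM with galactose, 1024 ± 219 CPM with glucose and 1700 ± 196 CPM with lactose (SD, n = 13), and all 13 mice showed each difference. The edgeR log2 differences were -0.77 for galactose against glucose (adjusted p = 2.83e-05) and 0.73 for lactose against glucose (adjusted p = 2.28e-05), and lactose was 2.83-fold above galactose (adjusted p = 2.9e-12). Slc2a5, the fructose transporter, rose only with lactose, at 576 ± 169 CPM against 360 ± 107 CPM with glucose and 351 ± 151 CPM with galactose. Its log2 difference was 0.68 against glucose (adjusted p = 0.011) and 0.72 against galactose (adjusted p = 0.00345), in 13 of 13 mice each. Galactose against glucose was not called for Slc2a5 (log2 -0.04, adjusted p = 0.938), and the direct test of the 2 sugars passed. The Slc2a5 results passed in neither run alone (adjusted p = 0.389 within title numbers 1 to 18 and 0.0871 within 49 to 69 against glucose, and 0.0809 and 0.0816 against galactose). They did not pass with the tissue score as a covariate either (log2 0.60, adjusted p = 0.0874, and 0.56, adjusted p = 0.224).

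Sucrase-isomaltase and the main apical and basolateral glucose carriers were not called. Sis measured 5084 ± 945, 5802 ± 931 and 5932 ± 1055 CPM with glucose, galactose and lactose. Slc5a1 measured 3941 ± 1212, 4615 ± 1285 and 5210 ± 1124 CPM, and Slc2a2 704 ± 162, 801 ± 152 and 752 ± 140 CPM in the same order. The edgeR adjusted p values for galactose against glucose were 0.282, 0.421 and 0.355, and for lactose against glucose 0.126, 0.071 and 0.589. Among enzymes that take galactose into glucose metabolism, Galk1 fell by 0.33 with galactose (46.9 ± 6.18 against 59.1 ± 7.49 CPM, adjusted p = 0.00484, 12 of 13 mice). Galt (43.2 ± 2.56 CPM with glucose) was called in no comparison.

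**Figure D1:**
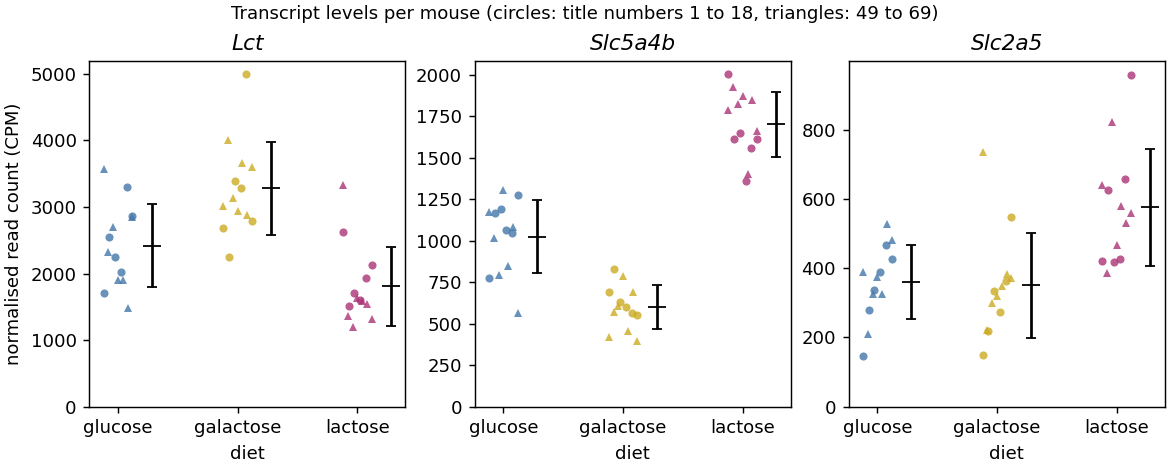
Normalised read counts (CPM, vertical axis) of Lct, Slc5a4b and Slc2a5 in each mouse by diet (horizontal axis), with mean ± SD of 13 mice beside the points, circles for title numbers 1 to 18 and triangles for 49 to 69. Mean Lct falls from 3281 CPM with galactose to 1806 CPM with lactose, and mean Slc5a4b rises from 600.5 to 1700 CPM.

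Replacing 16 en% of glucose by galactose was accompanied by less mRNA for enzymes of detoxification and fat oxidation. Ptgr1, a reductase of reactive aldehydes and ketones, was 3.13-fold lower with galactose, at 260 ± 110 CPM against 815 ± 324 CPM (SD, n = 13; log2 -1.65, SE 0.20, edgeR adjusted p = 7.56e-06). The aldo-keto reductase Akr1b8 fell by 2.02 on the log2 scale (172 ± 114 against 699 ± 274 CPM, SE 0.28, adjusted p = 2.24e-05). Sod1, superoxide dismutase, fell 1.68-fold to 476.5 ± 66.5 CPM. Hsd17b11, a dehydrogenase of lipid droplets, fell 1.98-fold to 1248 ± 241 CPM. Gal3st2b, a galactose sulfotransferase, fell 1.60-fold, and the esterase Esd fell 1.61-fold. All 13 galactose mice lay below the glucose mean for each of these genes. EdgeR called 597 genes, 177 higher and 420 lower, and 20 of the higher and 37 of the lower differed more than 2-fold. The balance of directions depended on scaling, as library totals in place of TMM gave 315 higher and 286 lower.

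Genes that rose with galactose had varied functions. Gpr151, an orphan receptor, rose 2.10-fold (5.17 ± 1.37 against 2.47 ± 0.965 CPM, edgeR adjusted p = 8.88e-04, 13 of 13 mice). Acox3, a peroxisomal oxidase of branched fatty acids, rose 1.39-fold (adjusted p = 3.51e-04, 12 mice), Lpar1 1.29-fold, Dlg1 1.19-fold and Slc35e1 1.18-fold. Axin2, a Wnt target, rose 1.51-fold (15.0 ± 3.24 against 9.91 ± 3.72 CPM, adjusted p = 0.028, 12 mice). Rnase1 was also called (log2 4.68), but galactose 4 decided its value, which was 0.90 without that library (adjusted p = 0.189). The same library decided Pnliprp1 (log2 6.42, 1.84 without it), Clps (3.59, 0.33 without it), Nupr1 (2.31, 0.38 without it) and Klk1 (2.19, 0.15 without it), and none of these passed without it.

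Fat oxidation had the smallest camera p of the lists. Of 32 tested genes of fatty acid oxidation and ketogenesis, 24 were lower with galactose, none was higher and 8 did not pass, and 29 were lower when adjusted over the list alone. The peroxisomal thiolase Acaa1b measured 355 ± 156 CPM against 851 ± 242 CPM (log2 -1.26, edgeR adjusted p = 8.16e-05). Eci1 fell by 0.66 (adjusted p = 2.56e-05), Acadvl by 0.39 and Hadha by 0.41, each in 13 of 13 mice, and Cpt1a and Acadm were among the other members that fell. The list passed camera (median log2 -0.45, adjusted p = 7.98e-37), with adjusted p = 0.00888 with an estimated correlation. The median was -0.53 within title numbers 1 to 18, where 11 members were lower, and -0.40 within 49 to 69, where 6 were lower. When the tissue score was a covariate, 16 members were still lower.

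Glutathione and xenobiotic enzymes shared this direction. Among 28 NRF2 target and xenobiotic genes 12 were lower with galactose, none was higher and 16 did not pass, while 2 were higher and 19 lower adjusted over the list alone. Gsta3 fell by 1.28 (69.7 ± 31.2 against 169 ± 49.8 CPM, edgeR adjusted p = 2.87e-05), Gsta2 by 1.53, Gsta1 by 0.67 and Gclm, a subunit of the enzyme that starts glutathione synthesis, by 0.55. Camera gave adjusted p = 8.38e-15 (median log2 -0.38), and adjusted p = 0.0678 with an estimated correlation. In the pentose phosphate and polyol list 7 of 15 genes fell, none rose and 8 did not pass, with 8 lower adjusted over the list alone. They included Tkt (log2 -0.51), Taldo1 (-0.40), Pgd (-0.59) and Akr1b8. Camera gave adjusted p = 2.22e-10 (median -0.17), and adjusted p = 0.00888 with an estimated correlation.

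Enzymes around UDP-sugars fell as well, though the pathway did not move as a whole. Pgm1 fell by 0.87 (232 ± 63.3 against 426 ± 98.3 CPM, edgeR adjusted p = 5.93e-05), Ugdh by 0.59 and Ugp2 by 0.44, each in 13 of 13 mice, while 9 of 13 list genes did not pass and none rose. Adjusted over the list alone, 1 was higher and 4 lower. The Leloir and UDP-sugar list passed camera as lower (adjusted p = 0.00399), with adjusted p = 0.12 with an estimated correlation. Its mean was -0.17 and its median -0.01, which became 0.02 with library totals. In glycolysis Pfkl, Aldoa and Pgk1 fell and the hexokinase Hk3 rose 1.41-fold, of 23 tested genes. Of 21 lipogenic targets of ChREBP and SREBP-1, 3 fell, none rose and 18 did not pass, with 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0388, median -0.07; adjusted p = 0.795 with an estimated correlation). Me1 fell by 0.94, Acacb by 1.34 and Srebf1 by 0.62, the last at -1.14 within title numbers 1 to 18 and -0.14 within 49 to 69. Fatty acid carriers Fabp1 (log2 -0.51) and Fabp2 (-0.45) and the droplet coat gene Plin2 (-0.49) also fell, with the lipid absorption list not past camera (adjusted p = 0.107).

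Several further lists passed camera without a single called member, and each had adjusted p = 0.795 with an estimated correlation. Smooth muscle genes had a median log2 of 0.49 (camera adjusted p = 1.24e-04; 8 of 12 higher adjusted over the list alone), but 0.78 within title numbers 1 to 18, 0.10 within 49 to 69 and -0.05 with the tissue score as a covariate. Synpo2 (log2 0.49, adjusted p = 0.0773) did not pass. Interferon response genes had a median of 0.51 (camera adjusted p = 7.89e-04; 29 tested), at 1.53 within 1 to 18 and 0.23 within 49 to 69, and Iigp1 did not pass (log2 0.36, adjusted p = 0.0615). B and plasma cell genes had a median of -0.48 (camera adjusted p = 0.00378; 4 of 13 lower adjusted over the list alone), with Igha at -0.54 and Jchain at -0.55 not passing (adjusted p = 0.0735 and 0.0745). Myeloid (0.17, camera adjusted p = 0.00104), fibroblast (0.23, 0.00145), peptide digestion (0.16, 0.00399), cholesterol synthesis (0.15, 0.0388) and T cell genes (0.17, 0.0402) leaned higher, and oxidative phosphorylation genes lower (-0.08, 0.00145). Adjusted over the list alone, 3 myeloid genes and 1 fibroblast gene were higher and no gene of the other 4 lists or of the interferon list passed. Members such as Csf1r (log2 0.28, adjusted p = 0.0734), Mep1b (0.24, 0.161), Trdc (0.38, 0.2), Fbln1 (0.27, 0.0688) and Ndufb5 (-0.15, 0.0779) did not pass.

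Within title numbers 1 to 18 alone 72 genes were called and within 49 to 69 alone 179, with 6 and 7 mice per diet. All 58 named genes called with galactose had the same sign in both runs, 19 passed within the first and 29 within the second. With the tissue score as a covariate the count was 255, and 41 of the 58 still passed.

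**Figure D2:**
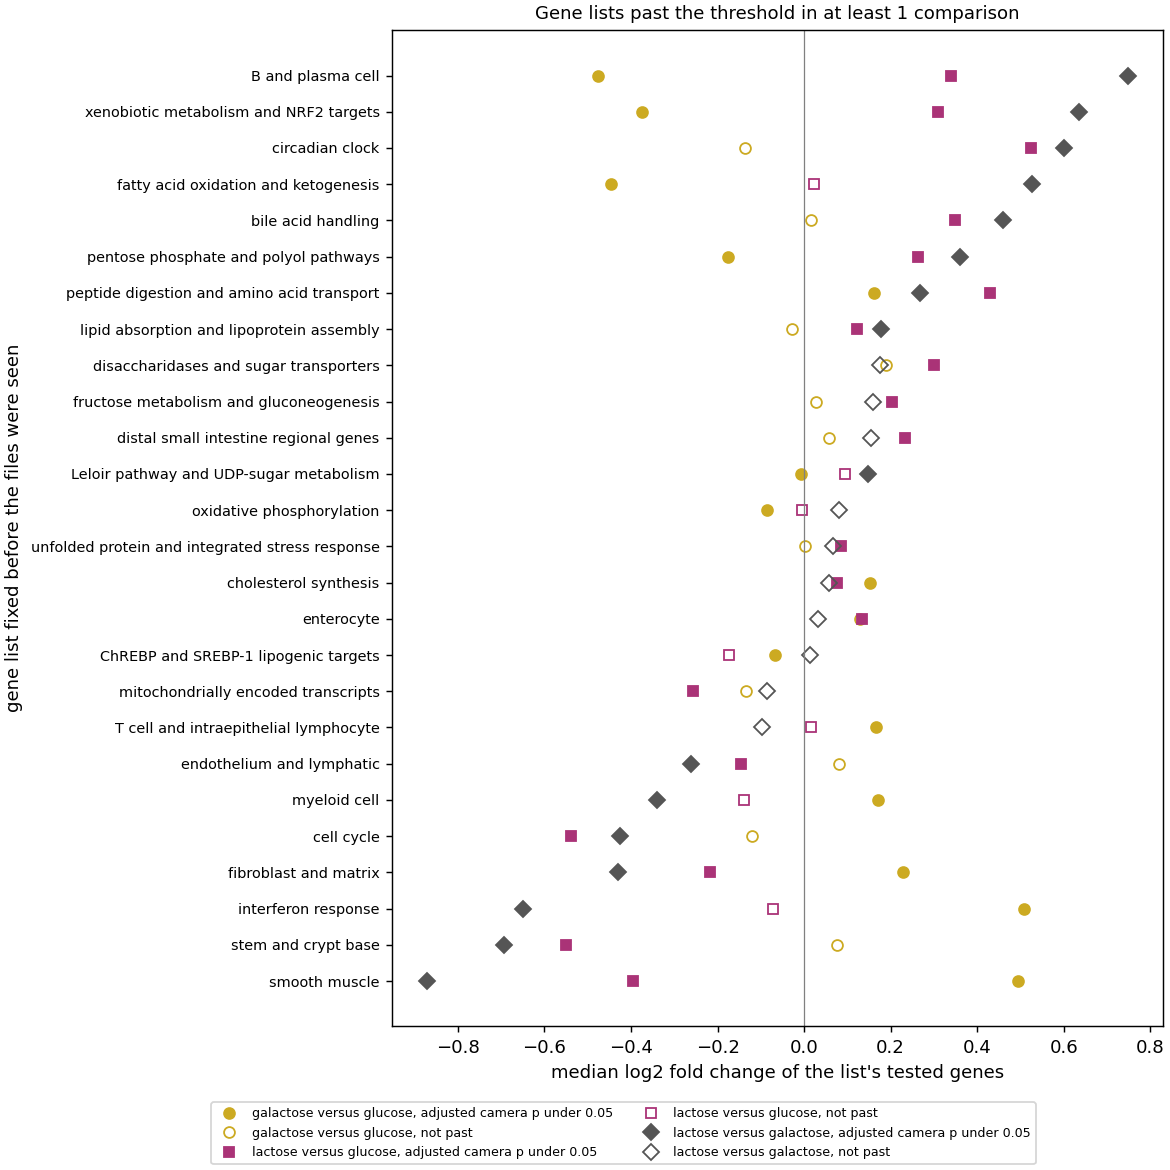
Median log2 fold change of the tested genes (horizontal axis) of each gene list past camera in at least 1 comparison (vertical axis), with filled symbols for lists past the threshold, circles for galactose against glucose, squares for lactose against glucose and diamonds for lactose against galactose. Fatty acid oxidation genes lie at -0.45 with galactose and at 0.02 with lactose, both against glucose, and smooth muscle genes at -0.87 for lactose against galactose.

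Lactose against glucose asked what the lactose diet changes, which differs from the glucose diet both in holding galactose and in the bond between the sugars. Pappa2, a protease of insulin-like growth factor binding proteins, was 21.5-fold higher with lactose, at 5.56 ± 3.40 CPM against 0.253 ± 0.208 CPM (SD, n = 13; log2 4.42, SE 0.39, edgeR adjusted p = 9.81e-10), and was 4.17 within title numbers 1 to 18 and 4.59 within 49 to 69. Aldh1l1, a folate enzyme, rose 1.85-fold (184 ± 23.3 against 99.7 ± 20.2 CPM), the adhesion receptor Adgrd1 2.84-fold and the nucleoside transporter Slc28a1 2.25-fold. Tmem229b fell 3.86-fold (13.3 ± 4.54 against 51.4 ± 37.2 CPM, adjusted p = 7.45e-07). The ketone body thiolase Acat1 fell 1.49-fold, the barrier gene Sprr2a3 2.32-fold and skeletal actin Acta1 9.63-fold (0.661 ± 0.394 against 6.44 ± 5.20 CPM). All 13 lactose mice showed each of these differences. EdgeR called 2281 genes, 1279 higher and 1002 lower, with 76 and 43 of them changed more than 2-fold. Galactose against glucose gave 597, but the order was not the same in the 2 runs, with 18 for lactose against 72 for galactose within title numbers 1 to 18, and 2019 against 179 within 49 to 69. With library totals in place of TMM 3527 were called, 623 higher and 2904 lower, and the median of all genes moved from -0.03 to -0.13.

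Brush-border peptidases and amino acid carriers rose with lactose. Dpp4, which trims dipeptides, measured 1120 ± 196 CPM against 687 ± 190 CPM (log2 0.71, SE 0.13, edgeR adjusted p = 3.66e-04), Enpep rose by 0.78, Anpep by 0.91 and the cystine carrier subunit Slc3a1 by 0.42, each in 13 of 13 mice. Of 23 genes of peptide digestion and amino acid transport 11 rose, none fell and 12 did not pass, and 16 rose when adjusted over the list alone. Camera gave adjusted p = 1.06e-10 (median 0.43), and adjusted p = 0.342 with an estimated correlation. No member passed within title numbers 1 to 18 and 15 did within 49 to 69, and 5 passed with the tissue score as a covariate.

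Further sugar-handling genes rose with lactose. Of 15 disaccharidase and sugar transporter genes 5 rose, 2 fell and 8 did not pass (7 higher and 2 lower adjusted over the list alone). Trehalase Treh rose by 0.41, the urate and hexose carrier Slc2a9 by 0.44 and the inositol carrier Slc5a11 by 0.42, while Lct and Slc2a8 (log2 -0.32) fell against the list. The list passed camera (adjusted p = 3.62e-04, median 0.30), with adjusted p = 0.418 with an estimated correlation. Fructose metabolism and gluconeogenesis had 4 higher, 1 lower and 7 not passing of 12 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0218, median 0.20; adjusted p = 0.418 with an estimated correlation), with Pcx up by 0.28, Fbp2 up by 0.20 and G6pc down by 0.74 against the list. With library totals no member of that list was higher. In the Leloir and UDP-sugar list Ugp2 rose by 0.52, Ugdh by 0.40 and Galm by 0.21, glycogen synthase Gys1 fell by 0.22, and the list did not pass camera (adjusted p = 0.12).

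Genes of the pentose phosphate and NRF2 lists rose, opposite to galactose. Tkt rose by 0.41, the sorbitol enzyme Sord by 0.68 and Akr1b7 by 0.88, and Akr1b10 fell by 0.51 against the list, so that 6 of 15 genes were higher, 1 lower and 8 not passing (8 and 1 adjusted over the list alone; camera adjusted p = 5.01e-04, median 0.26; adjusted p = 0.342 with an estimated correlation). Gsta3 rose by 0.74 (283 ± 48.3 against 169 ± 49.8 CPM, edgeR adjusted p = 0.00438, 13 mice), Gpx2, a glutathione peroxidase, by 0.75, Ces2e by 0.30 and Ugt2b34 by 0.40. In that list 9 of 28 genes rose, none fell and 19 did not pass, with 15 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.72e-08, median 0.31; adjusted p = 0.342 with an estimated correlation). Fat oxidation did not follow, with 3 genes higher, 2 lower and 27 of 32 not passing (median 0.02, camera adjusted p = 0.595).

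Stem and crypt base markers fell with lactose. Lgr5, the marker of crypt base stem cells, measured 2.23 ± 0.780 CPM against 4.38 ± 0.788 CPM (log2 -0.97, SE 0.14, edgeR adjusted p = 1.32e-05, 13 of 13 mice). Prom1 fell by 0.60, the proliferation-linked Cdca7 by 0.85 and Axin2 by 0.51, so 4 of 12 genes fell, none rose and 8 did not pass, with 4 lower adjusted over the list alone. Camera gave adjusted p = 0.00337 (median -0.55), and adjusted p = 0.628 with an estimated correlation. The median was -0.28 within title numbers 1 to 18, -0.66 within 49 to 69 and -0.13 with the tissue score as a covariate, where 1 member passed. In the cell cycle list Ccne2 fell by 0.71 and Cenpa by 0.93, none rose and 31 of 33 did not pass (1 lower adjusted over the list alone; camera adjusted p = 3.62e-04, median -0.54; adjusted p = 0.661 with an estimated correlation). Fibroblast genes (median -0.22, camera adjusted p = 0.013) had only Col1a1 lower (log2 -0.39, adjusted p = 0.0257) of 13. Smooth muscle (-0.40, camera 0.0218) and endothelial genes (-0.15, camera 0.0298) had none called, also when adjusted over the list alone, and Des (log2 -0.51, adjusted p = 0.0923) and Cdh5 (-0.22, 0.131) did not pass. These 3 had adjusted p = 0.661 with an estimated correlation.

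Plasma cell transcripts rose with lactose. Igha, the heavy chain of IgA, measured 1518 ± 491 CPM with lactose and 990 ± 243 CPM with glucose (log2 0.62, edgeR adjusted p = 0.0155), Jchain rose by 0.67 (adjusted p = 0.0103) and Igkc by 0.76 (adjusted p = 0.00573), each in 11 of 13 mice. Tnfrsf17 rose too, so 4 of 13 B and plasma cell genes were higher, none lower and 9 not passing (5 higher adjusted over the list alone; camera adjusted p = 0.0269, median 0.34; adjusted p = 0.661 with an estimated correlation). Bile acid carriers rose as well. Slc10a2, the ileal uptake carrier, was 2.07-fold higher at the low level of 0.775 ± 0.265 CPM (adjusted p = 7.08e-04, 13 mice), Slc51a rose by 0.42, Abcc2 by 0.39 and Slc51b by 0.35. This list had 4 higher, none lower and 3 of 7 not passing (4 adjusted over the list alone; camera adjusted p = 0.00201, median 0.35), with adjusted p = 0.0447 with an estimated correlation. The distal small intestine list, which shares Slc51a, Slc51b and Slc10a2 with it, had those 3 higher of 10 and none lower (4 adjusted over the list alone; camera adjusted p = 0.0218, median 0.23; adjusted p = 0.451 with an estimated correlation).

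Lipid handling moved in parts. Fabp2 rose 1.45-fold with lactose (12210 ± 1949 against 8412 ± 2337 CPM, edgeR adjusted p = 0.00173, 12 mice), and Soat2 (log2 0.36), Dgat1 (0.20) and Mttp also rose, so that 6 of 24 lipid absorption genes were higher and none lower (camera adjusted p = 0.0218, median 0.12). Cd36 was called (log2 0.91, adjusted p = 0.0164, 7 of 13 mice), but was -0.22 within title numbers 1 to 18 and 1.54 within 49 to 69. In cholesterol synthesis Hsd17b7 rose by 0.29 (adjusted p = 0.0189), and 6 of 25 genes rose and none fell, with 8 adjusted over the list alone (camera adjusted p = 0.0298, median 0.08), but 1 with library totals. The elongases Elovl6 (log2 -0.85) and Elovl5 (-0.55) and ChREBP itself, Mlxipl (-0.38), fell, and Mlx (0.26) rose, in a lipogenic list not past camera (adjusted p = 0.12). Unfolded protein response genes had 4 of 24 higher and none lower (Dnajb9 by 0.36, Trib3 by 0.60, Herpud1 by 0.46 and Atf4 by 0.22; camera adjusted p = 0.0218, median 0.08). The enterocyte list had 4 of 15 genes higher, Fabp2, Mttp and Anpep among them, and Lct lower (camera adjusted p = 0.0301, median 0.13), and mitochondrially encoded genes had mt-Nd2 lower (log2 -0.48), of 15 (camera adjusted p = 0.032, median -0.26). The lists past camera in this group each had adjusted p = 0.661 with an estimated correlation. Adjusted over the list alone, 5 enterocyte genes were higher and 1 lower, and the lipid, unfolded protein and mitochondrial counts stayed at 6, 4 and 1.

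A few clock genes rose with lactose. Cry2 rose by 0.86 (21.7 ± 8.03 against 11.9 ± 4.56 CPM, edgeR adjusted p = 0.00144, 12 mice), Wee1 by 0.72 and Cry1 by 0.44. Of 20 clock genes 3 rose, none fell and 17 did not pass, also when adjusted over the list alone (camera adjusted p = 8.92e-04, median 0.52; adjusted p = 0.418 with an estimated correlation). The median was 0.09 within title numbers 1 to 18 and 0.76 within 49 to 69, but no gene passed a test of diet by run interaction. Dbp, an output gene of the clock, did not pass (log2 0.84, adjusted p = 0.344). Across mice, with the diet means removed, Dbp followed the title number in the first run (rho 0.814, permutation p = 4e-05; r 0.857, p = 2e-05) and less in the second (rho 0.286, p = 0.208; r 0.365, p = 0.103). Arntl ran the other way (rho -0.93, p = 1e-05, the smallest the resamples can give; r -0.921 in the first run, and rho -0.404, p = 0.0697; r -0.456, p = 0.0379 in the second). Without the 2 mice whose title numbers lay farthest from the middle of the run, r was 0.843 and 0.442 for Dbp and -0.898 and -0.497 for Arntl. After adjustment over these 4 relations p for rho was 8e-05 and 0.208 for Dbp and 4e-05 and 0.0929 for Arntl, and p for r was 4e-05 and 0.103 for Dbp and 4e-05 and 0.0505 for Arntl, so no relation in the second run passed.

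**Figure D3:**
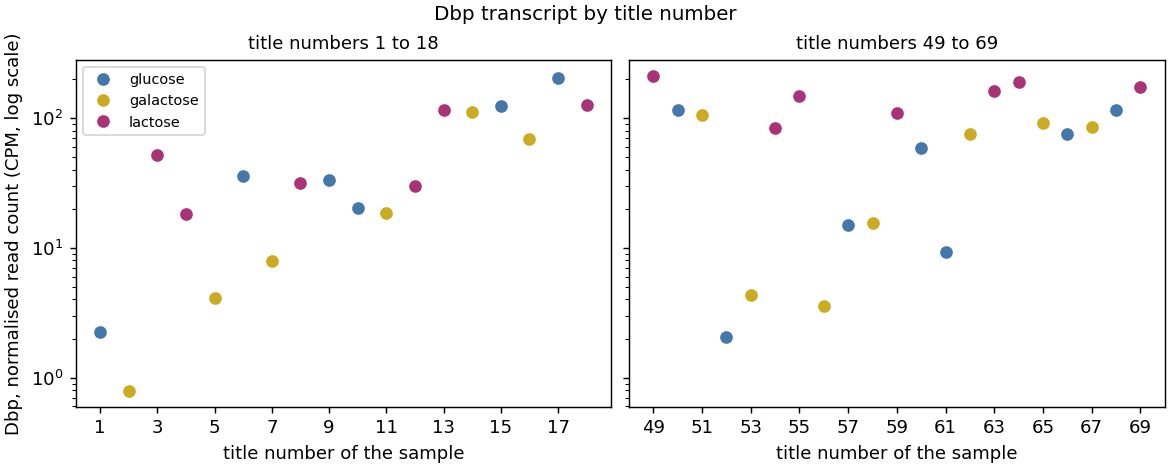
Normalised read count of Dbp (CPM, log scale, vertical axis) in each mouse by title number (horizontal axis), coloured by diet, with title numbers 1 to 18 at the left and 49 to 69 at the right. Dbp climbs with the number in the first run (rho 0.814), and the relation is weaker in the second (rho 0.286).

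For lactose against glucose 18 genes passed within title numbers 1 to 18 and 2019 within 49 to 69. Of 104 named genes called with lactose against glucose 103 had the same sign in both runs, with Cd36 the exception, while 8 passed within the first run and 75 within the second. A test of diet by run interaction in edgeR called 0 genes in each comparison, with 634, 894 and 902 genes at unadjusted p under 0.05. With the tissue score as a covariate 617 genes were called, and 45 of the 104 still passed.

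Lactose against galactose set the bound sugars against the free ones, and it gave the largest number of changed genes. Ptgr1 was 5.69-fold higher with lactose than with galactose (1480 ± 416 against 260 ± 110 CPM, SD, n = 13; log2 2.51, SE 0.21, edgeR adjusted p = 5.96e-11). Sod1 was 2.17-fold higher (1036 ± 145 against 476.5 ± 66.5 CPM), Tkt 1.89-fold, Gal3st2b 2.06-fold and Pappa2 28.6-fold. Lower with lactose were Acta1 (33.2-fold, from 22.2 ± 18.9 CPM), Tmem229b (4.89-fold), Tlcd2 (2.20-fold), the metalloprotease Adam15 (1.46-fold), the glucosidase Pgghg (1.85-fold) and Xk (1.83-fold). All 13 lactose mice showed each of these differences. EdgeR called 4532 genes, 2328 higher and 2204 lower, with 230 and 159 of them changed more than 2-fold. With library totals 6021 were called, 1064 higher and 4957 lower, and the median of all genes moved from -0.02 to -0.16. The pancreatic gene Pnliprp1 was lower at log2 -8.75, a value decided by galactose 4 and -4.19 without it (adjusted p = 0.00157), where galactose 7 remained.

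Detoxification and fat oxidation genes were higher with lactose than with galactose. Gsta3 was 4.06-fold higher with lactose (283 ± 48.3 against 69.7 ± 31.2 CPM, edgeR adjusted p = 2.91e-10), Gsta2 5.67-fold, Gsta1 1.96-fold and Gclm 1.69-fold. Of 28 NRF2 and xenobiotic genes 22 were higher, only Cyp2c55 lower (log2 -0.93, against the list) and 5 not passing, with 24 and 1 adjusted over the list alone. Camera gave adjusted p = 2.93e-20 (median 0.64), and adjusted p = 0.022 with an estimated correlation. Eci2, an isomerase for unsaturated fatty acids, was higher by 0.98 (176.5 ± 56.8 against 89.2 ± 12.7 CPM, adjusted p = 1.13e-07), Acadm by 0.39 and Cyp4a31 by 3.50 at 1.60 ± 1.22 CPM, each in 13 of 13 mice. Of 32 fat oxidation genes 24 were higher, only the ketone body gene Bdh1 lower (log2 -0.26) and 7 not passing, with 27 and 1 adjusted over the list alone. The list passed camera (adjusted p = 3.81e-16, median 0.53), with adjusted p = 0.119 with an estimated correlation. Its median was 0.43 within title numbers 1 to 18 and 0.59 within 49 to 69. With the tissue score as a covariate 16 NRF2 and 10 fat oxidation genes were higher, and 1 gene of each list lower.

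Sugar phosphate and UDP-sugar enzymes were higher with lactose. G6pdx, the entry enzyme of the pentose phosphate pathway, was 2.01-fold higher, Akr1b8 5.13-fold and Taldo1 1.45-fold, and with Tkt 12 of 15 genes were higher, Akr1b10 alone was lower (log2 -0.61) and 2 did not pass. The counts were the same adjusted over the list alone, and the list passed camera (adjusted p = 5.37e-12, median 0.36), with adjusted p = 0.00809 with an estimated correlation. Ugdh (log2 0.99), Pgm1 (1.26) and Ugp2 (0.97) were higher in all 13 mice, and Galk1 by 0.21 in 10 (adjusted p = 0.0291, and 0.07 with library totals). Of 13 Leloir and UDP-sugar genes 6 were higher, Gys1 (-0.29) and Pgm2l1 (-0.43) lower and 5 not passing, as when adjusted over the list alone (camera adjusted p = 0.00245, median 0.15; adjusted p = 0.0775 with an estimated correlation). Abcc3 (log2 0.84), Abcc2 (0.71), Slc51a (0.40) and the bile acid receptor Nr1h4 (0.48) made 4 of 7 bile acid genes higher and none lower, with 5 adjusted over the list alone (camera adjusted p = 0.00245, median 0.46; adjusted p = 0.022 with an estimated correlation). Fabp2 was 1.98-fold higher and Apob lower (log2 -0.25), with 9 of 24 lipid absorption genes higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.0029, median 0.18; adjusted p = 0.621 with an estimated correlation). Among peptidases Enpep was higher by 0.74, and by 0.39 with the tissue score as a covariate, and Dpp4 by 0.59. In that list 8 of 23 were higher, Slc38a2 was lower (log2 -0.36) and 14 did not pass, with 11 and 1 adjusted over the list alone (camera adjusted p = 0.00271, median 0.27; adjusted p = 0.71 with an estimated correlation). No peptidase list member passed within title numbers 1 to 18 or with the tissue score as a covariate.

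Muscle, matrix and stem cell transcripts were lower with lactose than with galactose. Des, which encodes desmin, was 2.10-fold lower (18.4 ± 6.39 against 38.5 ± 25.3 CPM, edgeR adjusted p = 2.17e-04), Actg2 2.21-fold, Tagln 1.87-fold and Synpo2 1.79-fold, and all 12 smooth muscle genes were lower, also adjusted over the list alone (camera adjusted p = 1.67e-05, median -0.87; adjusted p = 0.506 with an estimated correlation). Col1a1 was 1.52-fold and Col3a1 1.46-fold lower, with 11 of 13 fibroblast genes lower and none higher by either adjustment (camera adjusted p = 4.13e-05, median -0.43; adjusted p = 0.462 with an estimated correlation). Lgr5 was lower by 1.07 (2.23 ± 0.780 against 4.67 ± 0.824 CPM, adjusted p = 3.19e-07), Axin2 by 1.10, Prom1 by 0.66 and Rnf43 by 0.34, and 6 of 12 stem genes were lower, none higher and 6 not passing (7 lower adjusted over the list alone; camera adjusted p = 0.00118, median -0.69; adjusted p = 0.506 with an estimated correlation). With the tissue score as a covariate no smooth muscle gene and 2 stem genes were lower, but the score itself is built from these lists. Within title numbers 1 to 18 7 smooth muscle and 4 stem genes were lower, and within 49 to 69 8 and 4 were.

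Immune transcripts split by cell type. Igha was 2.24-fold, Jchain 2.33-fold and Igkc 2.48-fold higher with lactose than with galactose, each in 12 of 13 mice, and 5 of 13 B and plasma cell genes were higher and none lower, also adjusted over the list alone (edgeR adjusted p = 5.81e-06 for Igha; camera adjusted p = 3.6e-04, median 0.75; adjusted p = 0.506 with an estimated correlation). Myeloid genes were lower, among them Csf1r (log2 -0.54), Cd68 (-0.41), Mrc1 (-0.39) and Itgax (-0.39), with 9 of 14 lower and Itgam higher (0.29) against the list (1 and 10 adjusted over the list alone; camera adjusted p = 0.00271, median -0.34; adjusted p = 0.621 with an estimated correlation). Endothelial genes had 6 of 14 lower, Tek (-0.37) and Pecam1 (-0.27) among them, and none higher (10 adjusted over the list alone; camera adjusted p = 0.00271, median -0.26; adjusted p = 0.621 with an estimated correlation). Iigp1 (-0.73), Gbp2 (-0.52) and Ifit2 (-1.55) were lower among 29 interferon genes, with none higher and 26 not passing (2 lower adjusted over the list alone; camera adjusted p = 0.00367, median -0.65; adjusted p = 0.886 with an estimated correlation). The interferon list was not tested without the 7 libraries high in interferon-induced transcripts. In the cell cycle list Ccne2 (-1.02), Mcm4 (-0.50) and Cdc6 (-0.40) were lower, none higher and 30 of 33 not passing (2 adjusted over the list alone; camera adjusted p = 0.0262, median -0.43; adjusted p = 0.893 with an estimated correlation). Clock genes had 6 of 20 higher, with Cry2 at 1.24, Wee1 at 0.88, Ciart at 2.83 and Per1 at 0.88, and Arntl (-1.12) and Nfil3 (-1.18) lower (10 and 2 adjusted over the list alone; camera adjusted p = 0.00328, median 0.60; adjusted p = 0.506 with an estimated correlation). The clock median was 0.31 within title numbers 1 to 18 and 0.91 within 49 to 69. The clock score did not pass (permutation adjusted p = 0.0836, with mice not paired by triplet).

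Within the runs 950 and 2932 genes were called for lactose against galactose. Of 150 named calls with a value in both runs 149 had the same sign, with Cyp3a11 the exception (log2 0.48 in all mice, -0.03 within 1 to 18), and 78 passed within the first and 115 within the second. With the tissue score as a covariate 801 genes were called, and 59 of the 151 named genes still passed.

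Galactose and lactose moved many genes in opposite directions from glucose. Of the genes called against glucose 138 were in both lists, and 105 of these had opposite signs. In 88 galactose was lower and lactose higher than glucose, against 36.7 by chance, and in 17 the order was reversed, against 12.1. Only 33 had the same sign, 18 higher (15.4 by chance) and 15 lower (28.7). Slc5a4b, Gsta3, Tkt, Ugdh and Fabp2 were among those lower with galactose and higher with lactose, and Axin2 among those higher with galactose and lower with lactose.

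The glucose mice were the control of both comparisons, which alone pushes both fold changes the same way. Across all genes the fold changes had r = -0.0649 (-0.102 for 8302 genes at log2 CPM of at least 3). Simulated groups without change had a mean r of 0.492 (range -0.0141 to 0.826 in 1000 draws). With the glucose mice split into separate controls, mean r was -0.21, and 29.9 genes were opposite and 0.333 alike on average in 15 splits. The same sign was seen in 51.7% of genes, against 66.7% in the simulated groups. At adjusted p under 0.1 edgeR gave 106 shared genes with the same sign and 230 with opposite signs. The tissue score was also opposed, at 0.512 with galactose, 0.0393 with glucose and -0.551 with lactose. Its difference between galactose and glucose did not pass (permutation adjusted p = 0.0711). Tissue content may therefore carry part of the opposition. With the score as a covariate the calls against glucose fell to 255 for galactose and 617 for lactose. The overlap and correlation were not computed with it.

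**Figure D4:**
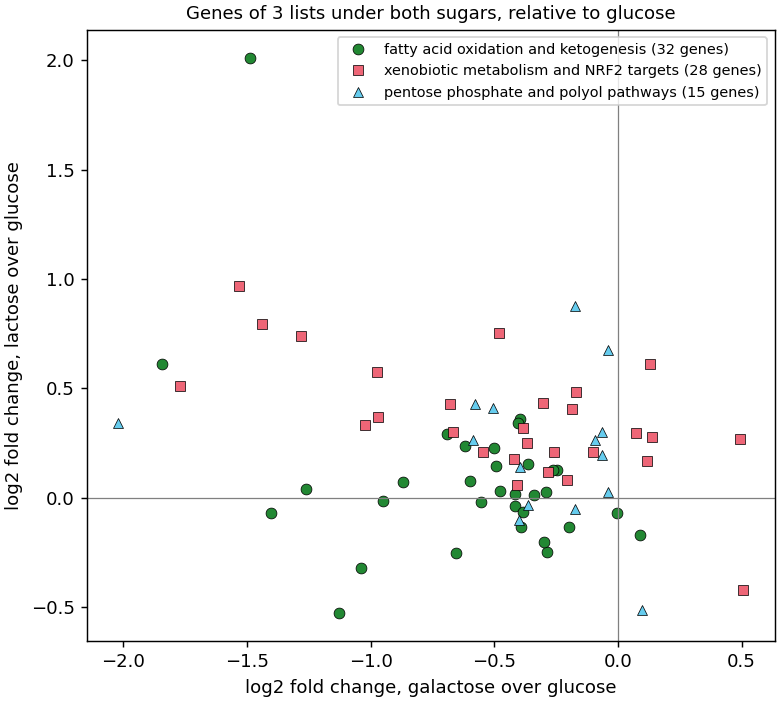
Log2 fold change of galactose against glucose (horizontal axis) and of lactose against glucose (vertical axis) for tested genes of 3 lists, 32 of fatty acid oxidation (circles), 28 NRF2 and xenobiotic (squares) and 15 of the pentose phosphate and polyol pathways (triangles). Medians on the horizontal axis are -0.45, -0.38 and -0.17, and on the vertical axis 0.02, 0.31 and 0.26.

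The test of any difference between the 3 diets called 4437 genes in edgeR, with 6331 at unadjusted p under 0.05. Within title numbers 1 to 18 it called 510, within 49 to 69 it called 3168, and with the tissue score as a covariate 1050.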

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

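The tests of plasma cell transcripts, of the whole stem list and of Dbp against title number, and the covariates for the tissue score and the title number were chosen after the results were seen. Lactose and galactose moved 105 genes in opposite directions from glucose, and Lct differed by -0.86 between the 2 sugars. Random splits argue against chance as the source of the numbers of changed genes, within what 60 splits can show. The splits did not keep 1 mouse of each diet per triplet of title numbers. Of 60 splits of the mice into groups of the same sizes, the real one included, only 1 gave as many genes as the real diets in each comparison, the smallest share these splits can give. The highest other counts were 275 against 597 for galactose and glucose, 272 against 2281 for lactose and glucose, 758 against 4532 for lactose and galactose, and 174 against 4437 for any diet.

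Fat oxidation and NRF2 genes were lower with galactose than with lactose, with a median log2 of 0.60 over 60 genes, and 3 technical explanations were tested. The median was 0.61 with a regional score as a covariate, where 46 of 60 genes passed in that direction. This argues against a shift of the scraped segment as the cause, as far as these marker genes measure it. The distal list itself had a median of 0.15 and the proximal list of -0.30 for lactose against galactose (camera adjusted p = 0.287 and 0.882). The median of the 60 genes was 0.45 under the scaling least favourable to it, where 42 passed, which argues against scaling as the cause. With the tissue score as a covariate it was also 0.45 (SE of the median 0.118, and 0.12 without it, both over genes), and only 26 of the 60 did. Estimates shrank and the median SE of single genes grew from 0.114 to 0.151. Tissue content may carry part of the difference. The score did not take up all of it, but it measures tissue content only through marker genes. The share due to tissue content therefore cannot be told. A hypothesis left open is that free galactose and lactose differ in how they set PPAR-alpha and NRF2 activity, which could be tested by protein and activity measurements or by feeding both sugars with PPAR-alpha absent.

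Stem cell, muscle and matrix transcripts were lower with lactose than with galactose, and shallower scraping of the lactose mice would give this without any effect on cells. With a crypt score as a covariate the median of Lgr5, Axin2, Prom1 and Rnf43 was -0.77, from -0.86 without it, but these 4 were picked among the called genes, so this decides nothing. Over all 12 stem genes the median went from -0.69 to -0.20 (SE of the median 0.172), but the 6 genes lower without the score still passed as lower and 2 passed as higher, so this median over genes going both ways decides nothing. For smooth muscle and matrix genes the median was -0.59, from -0.53, and 23 of 25 passed. Igha, Jchain and Igkc, from plasma cells below the epithelium, were higher with lactose by a median of 1.22, but were picked the same way. The whole B and plasma cell list had a median of 0.75 (SE of the median 0.136), with 5 of 13 genes higher. Shallower scraping that lost all tissue below the epithelium alike would not give this. But 9 of 14 myeloid, 6 of 14 endothelial and 11 of 13 fibroblast genes were lower, which it would. The plasma cell list was known to be higher when its test was chosen, so that test decides nothing about depth. The muscle and matrix median did not shrink, so the score of Paneth and cell cycle genes did not take it up. How far that score differs between diets was not measured, so this does not decide about crypt content. Less crypt in the scrapings stays open, as do less tissue from below the crypts and a true fall in stem cell or stromal transcripts.

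Of 20 clock genes 6 were higher and 2 lower with lactose than with galactose, and mice of each diet might have been collected at different hours. The clock score itself did not pass (difference 1.29, 9 of 13 mice, permutation adjusted p = 0.0836), and neither did Dbp (log2 1.29, edgeR adjusted p = 0.104). Neither test paired the mice of a triplet of title numbers, so a difference within triplets may have been missed. With the title number within each run as a covariate the median of the 6 clock genes that were higher was 1.06, from 0.97 without it. This test decides nothing, since each triplet of numbers held 1 mouse of each diet, so the covariate could not take up a diet difference. The number is linked to clock state in the first run, but rho of Dbp was 0.286 in the second. There the clock score was 1.92, 1.06 and 1.95 at title numbers 49 to 51. It was -2.32, -2.36 and -0.27 at 52 to 54, and 0.84, 3.00 and 2.12 at 67 to 69. The low rho therefore does not show that number and clock state are unrelated in the second run, and a break after 51 was not tested. Whether the numbers follow the hour of collection could not be decided. Feeding times that differ between diets are a second hypothesis, since food shifts the intestinal clock, and recorded collection and feeding hours would separate these.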

How the results depend on the processing

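Covariates for the title number, the tissue score and the clock score, and fits without certain libraries, were chosen after the results were seen. The cause of a change under an alternative was not tested unless said. Of 7109 alternative values of 357 named results 6317 kept their call and sign, 694 lost the call, 67 gained it and 31 turned sign. Only 6 of the 31 had been called (Cd36, Cyp3a11, Des, Tagln, Actg2 and Tek), and none was called after turning. For gene lists 82 of 147 alternative values kept the call and 65 lost it. The any-diet test on only 2 groups was not run, since it needs 3, and 60 splits were drawn.

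With library totals 3527 genes were called for lactose against glucose, Lct passed with galactose (0.48, adjusted p = 0.0356), and signs turned for Galt (0.0235 with galactose, -0.00168 with lactose, -0.0252 between the sugars), Slc2a2 with lactose (-0.00949) and Sis between the sugars (-0.10). Without a filter Lct did not pass with lactose (-0.42, adjusted p = 0.0661). With triplets as blocks galactose gave 908 genes and Lct passed (0.46, adjusted p = 0.0259). A residual component as covariate gave 1072 genes with galactose, 3482 with lactose, and Lct with galactose at 0.45 (adjusted p = 0.00809).

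Title numbers 1 to 18 alone gave 72, 18, 950 and 510 genes in the 3 comparisons and the any-diet test, from 6 mice per diet. There Lct with lactose was -0.34 (adjusted p = 0.555), and signs turned with galactose for Mep1b (-0.0242), with lactose for Cd36 (-0.22), and between the sugars for Cyp3a11 (-0.033). Title numbers 49 to 69 gave 179 genes with galactose and 2932 between the sugars, and Lct with lactose did not pass (-0.49, adjusted p = 0.11). Signs turned for Slc2a5 (0.0213) and Galt (0.0207) with galactose and Sis between the sugars (-0.0469).

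Lct with galactose also passed in fits of only the 2 groups (0.44, adjusted p = 0.0367), in DESeq2 (0.45, adjusted p = 0.0289), in voom (0.45, adjusted p = 0.0196), with the title number (0.46, adjusted p = 0.0307), with the clock score (0.48, adjusted p = 0.0333) and without the 3 libraries lowest on the first component (0.47, adjusted p = 0.0439). Voom called 1247 genes with galactose, and turned Slc2a5 with galactose (0.0454) and Sis between the sugars (-0.00959).

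The tissue score as a covariate left 255, 617, 801 and 1050 genes, and Lct with lactose did not pass (-0.36, adjusted p = 0.187). The score differs between diets, so it also takes up part of any diet effect. Signs turned with galactose for Slc2a5 (0.0413) and Galt (0.048), with lactose for Des (0.00236) and Synpo2 (0.036), and between the sugars for Sis (-0.0836), Slc5a1 (-0.0362), Galt (-0.0142), Des (0.0468), Tagln (0.18), Actg2 (0.21) and Tek (0.0112). The clock score as a covariate gave 1059 genes with galactose, and turned Slc2a5 with galactose (0.0696), and Sis (-0.0863) and Slc5a1 (-0.0696) between the sugars.

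Without galactose 4 Sis between the sugars was -0.00018. Without the interferon-high libraries Lct with lactose did not pass (-0.36, adjusted p = 0.136). Without the 3 libraries lowest on the first component Slc2a5 with galactose was 0.018, Galt with galactose 0.0246 and Sis between the sugars -0.0461. With the correlation estimated, 2, 1 and 3 gene lists passed in the 3 comparisons, and with fry 4 passed with galactose and 10 with lactose. At adjusted p under 0.1 the shared genes of the same sign numbered 106.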

Other observations

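Some amino acid and retinoid genes rose and others fell with lactose. Aldh4a1 and Glud1, which turn proline and glutamate toward the citric acid cycle, rose 2.00-fold (246 ± 60.7 against 123 ± 37.4 CPM, edgeR adjusted p = 1.2e-04) and 1.96-fold (722 ± 221 against 367 ± 140 CPM, adjusted p = 5.81e-04) over glucose. Aldh18a1, which makes proline and ornithine precursors, fell by 0.94 and Oat by 0.73, each in 13 of 13 mice (SD, n = 13). Of 24 amino acid catabolism genes 7 rose and 3 fell with lactose (camera adjusted p = 0.276). Between lactose and galactose 8 were higher and 4 lower, with a median of 0.05 and a mean of -0.05. Aldh1a1, which makes retinoic acid, measured 3907 ± 1110 CPM with lactose, 2369 ± 643 CPM with glucose and 1235 ± 417 CPM with galactose, and passed in all 3 comparisons (adjusted p = 1.96e-09 for lactose against galactose). Lrat, which stores retinol as esters, was lower with lactose than with galactose (log2 -0.67, adjusted p = 7.52e-05), and Retsat was higher (0.70). Isx, a repressor of carotenoid uptake, was called higher with lactose than with glucose (log2 2.75), with a wide spread of 11.7 ± 18.7 CPM and 11 of 13 mice in that direction. It was 0.96 within title numbers 1 to 18 (adjusted p = 0.389), 3.46 within 49 to 69, and 1.64 with the tissue score as a covariate (adjusted p = 0.0641). Of 14 retinoid genes 4 were higher and 1 lower with lactose than with glucose (camera adjusted p = 0.514, median -0.01, mean 0.20), and 4 were higher and 3 lower than with galactose (camera adjusted p = 0.588, median -0.09, mean 0.18).

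Some mineral and blood genes differed between the diets, though none of their lists passed camera. S100g, the calcium-binding protein of enterocytes, fell by 1.52 with galactose (60.1 ± 41.8 against 172 ± 93.7 CPM, edgeR adjusted p = 0.0133, 13 of 13 mice), while the calcium pump Atp2b1 rose by 0.39. Vdr, the vitamin D receptor, was 1.34-fold higher with lactose than with galactose (595 ± 88.5 against 443 ± 71.0 CPM), and the manganese carrier Slc30a10 1.78-fold lower. Ftl1, a ferritin chain, fell by 0.36 with galactose and was higher by 0.57 with lactose than with galactose. Hmox1, which breaks down heme, showed the same order (log2 -1.02 and 1.35), while the folate and heme carrier Slc46a1 (-0.73) and Ankrd37 (-0.76) were lower with lactose than with galactose. In that comparison 2 of 13 calcium genes were higher and 6 lower (camera adjusted p = 0.254), and 2 of 13 iron genes were higher and 2 lower (camera adjusted p = 0.882). Hba-a1 was 2.06-fold higher with lactose than with galactose at 5.52 ± 2.49 CPM (adjusted p = 0.00386, 13 mice), and 5 of 6 blood genes were higher and Pf4 lower (camera adjusted p = 0.0782).

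The tissue score covariate and the Dbp test were chosen after the results were seen. Hemoglobin and plasma cell transcripts were higher, and muscle and matrix transcripts lower, in the lactose group than in the galactose group. The make-up of the scrapings may therefore have differed in more than 1 way. The muscle and matrix median was -0.59 with the crypt score as a covariate, so that score did not take it up. Crypt content as its cause was not decided, and blood left in the tissue was not tested. Histology of the same segment, or counts of IgA plasma cells, would show whether cell numbers changed.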
